A study of Danio rerio with 16 samples.

How the data were processed

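The series holds 16 one-colour Agilent arrays of adult female zebrafish brain, 1 array per brain and per fish. The fish were of the AB wild type, were raised to 9 months after fertilization, and as embryos, from about 1 to 72 h after fertilization, had been kept in water that held the herbicide atrazine at 0.3, 3 or 30 ppb or none of it (0 ppb), with 4 fish per dose. Groups, doses and replicate numbers come from the sample labels.

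The scanner files hold 176026 non-control spots per array, which stand for 128291 probes. Per the file headers, the intensity used here was background-subtracted and spatially detrended within each array, and the arrays were not scaled to one another. Feature Extraction 12.0 was the scanner software per the submitters' processing notes. Per the file headers, each spot also carries 0 or 1 flags for well above background, saturated and outlier, which served as filters. The deposited value table of all arrays was identical to these intensity values (largest relative difference 0), so as an alternative source it gave no separate result. The authors also deposited 3 probe lists, 1 per dose, each with a fold change, its absolute ratio and its log2 value against 0 ppb. The test and the threshold behind the lists are not stated in them.

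From the intensities, log2 values were taken and each array's 75th percentile was subtracted. Control spots were left out, outlier spots were set to missing, and the spots of a probe were averaged. A probe was tested where it was well above background on at least 4 of the 16 arrays, which left 119712 probes. No spot was saturated. Signal over background stands in for depth: the share of spots well above background ran from 79.9% to 92.7% per array, and the SD of the log2 signal of repeated spots had array medians of 0.08 to 0.16. The number of arrays, 4 per group, limits the precision.

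Probes were named by matching the accession in the scanner files, without its version, to a RefSeq gene table (assembly GRCz12tu, used for names and for which genes neighbour each other). This named 39952 probes of 13547 genes, of which 13444 were tested. The other probes are identified by transcript, expressed-sequence or assembled-cluster identifiers that the table does not hold. Where a gene had several probes, the one with the highest mean signal stood for it.

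The groups were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8), with 1 mean per dose over all 16 arrays, no block, moderated two-sided tests and Benjamini-Hochberg adjustment over all probes tested, at an adjusted p under 0.05. The comparisons were each dose against 0 ppb, each pair of doses, a moderated F test over the 3 contrasts with 0 ppb, and a slope over equal dose steps. All effects are log2 differences with their standard error (SE), and group values are means ± SD over 4 arrays.

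Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, 1 probe per gene, two-sided, and Benjamini-Hochberg adjustment over 105 tests (35 lists and 3 doses). Camera with a correlation estimated per list and the rotation test fry were run beside it. The lists were the reproductive neuroendocrine axis, pituitary hormones, serotonin system, dopamine and noradrenaline system, GABA system, glutamate system, corticosteroid stress axis, hypothalamic neuropeptides, thyroid hormone signalling, immediate early genes, circadian clock, xenobiotic and oxidative stress response, DNA methylation and histone modification, heat shock response, endoplasmic reticulum stress, cholesterol synthesis, interferon and inflammatory response, microglia and macrophages, lymphocytes and neutrophils, oligodendrocytes and myelin, astroglia with radial glia and ependyma, neurons and synapse, cerebellum, cell cycle and neurogenesis, erythrocytes, blood vessel cells, meninges and connective tissue, skeletal muscle, retina with lens and pineal, skin and other epithelium, liver with yolk and ovary proteins, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, ion channels and calcium signalling, and insulin and growth factor signalling. A list needed 5 measured genes.

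The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes, for each dose against 0 ppb and each direction, up to 12 genes past the threshold with the largest change, with the probe well above background on all 4 arrays of at least 1 of both groups and all 4 treated arrays on the same side of the control mean. Where there were fewer than 10 it was topped up to 10 by the smallest unadjusted p, and such genes are given as values. It adds in each list up to 4 members past the threshold adjusted over the list alone, or else the 2 of smallest p, 23 genes of hormone, transmitter, stress, methylation, detoxification and activity pathways whatever their values, and the 5 genes of smallest p for the F test and the slope. Unnamed probes are given by identifier, at most 2 per direction.

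Same-numbered arrays shared a slide. Slides 1 and 2 were scanned on scan day 1 and slides 3 and 4 on scan day 2, each slide held all 4 doses, and each dose always took the same position on the slide, per the file headers. The deviations of same-numbered arrays from their group means correlated at r = −0.24 to 0.70 (median 0.54), above 0.1 in 20 of 24 pairs, against a median of −0.28 for arrays of different slides. Since the pairing comes from the slides, values with the slide as a replicate block and values within each scan day are given where they change a call.

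Correlations of fold changes between doses were set beside a simulation of unchanged groups that share the 4 controls, permuted groups, halved controls and, added later, doses exchanged within each slide and noise left after the replicate block. The random resampling steps used fixed seeds. The probe test was tested on simulated data for 0.3 against 0 ppb (118997 probes). With independent noise it recovered 0% of 1.5-fold, 11.9% of 2-fold and 57.6% of 4-fold changes. With the slide differences as measured it recovered 0%, 7.46% and 47.0% without a block and 2.99%, 23.9% and 57.6% with the replicate block, and the share of unchanged probes at an unadjusted p under 0.05 was 1.18% without and 4.96% with the block. A list raised by 0.5 log2 units (oligodendrocytes) in noise drawn independently for each gene was found by camera. The adjusted p was 8.58e-11 with the preset and 0.000441 with the estimated correlation, with 0 other lists past the threshold. This noise held no slide differences and no correlation between genes, so the 0 says nothing of false list calls on the real arrays. There, the 35 splits of each dose and the controls gave medians of 10, 7 and 9 lists past the preset test.

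Alternatives were a normexp background with an offset of 50, quantile and median scaling, no filter or a filter on all 16 arrays, blocks for slide and scan day, other variance models, array weights, fits of the 2 groups compared alone, other set tests, linear dose, and each array left out in turn. The normexp correction used the median spot signal, since the scanner files as used here hold no mean signal column. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.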

Results

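Whole-brain gene expression was measured on arrays in 16 adult females, 4 per embryonic atrazine dose. Median spot signal ran from 77.1 to 227 per array, the signal's 75th percentile from 447 to 799, and the signal of negative control spots from 22.3 to 51.1. The arrays differed more by slide than by dose. Component 1 held 62.1% of the variance, of which 72.6% lay between slides and 2.06% between doses, and component 2 held 6.50%, of which 89.6% lay between slides. Component 1 also rose with the log2 ratio of an array's 75th percentile to its median signal. It was −419 at a ratio of 1.55 in 0 ppb replicate 3 and 309 at 2.84 in 3 ppb replicate 2. On slide 1, 3 ppb replicate 1 lay at −136 and 2.16, the other arrays at 168 to 257 and 2.55 to 2.62. Whether component 1 reflects array signal or tissue was not tested. With limma's F test, 43133 of 119712 probes differed between slides and 47714 between scan days.

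**Figure D1:**
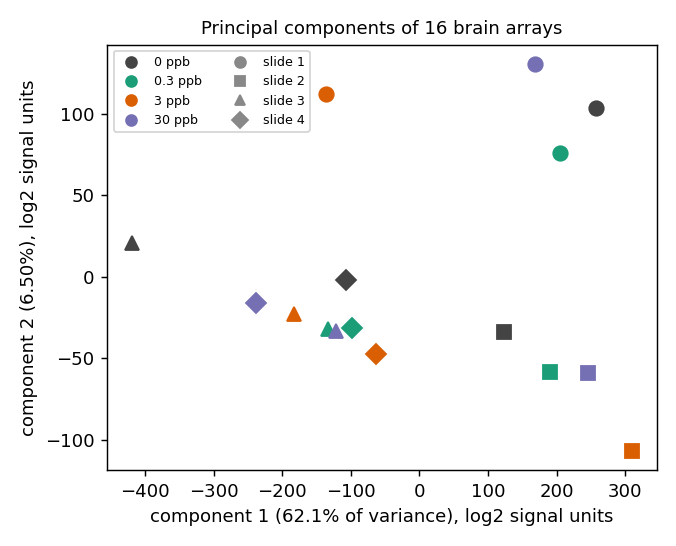
Each point is 1 brain on the first and second principal components of the log2 signal (log2 units), coloured by dose and shaped by replicate, which is the slide. Component 1 holds 62.1% of the variance, and 2.06% of it lies between doses.

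The first comparison set adult brains of fish kept at 0.3 ppb as embryos against those of controls. A transcript whose probe the authors describe as the cerebellar ataxia gene of the Cayman type (caytaxin a, an adaptor protein of neurons; probe A_15_P485237, ENSDART00000083474) was 4.03-fold higher, at 3.71 ± 0.25 against 1.70 ± 0.47 log2 signal in controls. A transcript first sequenced from testis (probe A_15_P251196, CO359592) was 8.10-fold higher, at −0.89 ± 0.42 against −3.91 ± 0.49. A further transcript without a gene name, A_15_P253096 (TC431332), given here after its values were seen, was 2.34-fold higher, at 2.15 ± 0.12 against 0.93 ± 0.16, and its sister probe A_15_P536812 differed by 1.08. In each of the 3, all 4 exposed brains lay above all 4 controls. Hypothalamic neuropeptide genes were lower as a group, with 23 of 25 measured members below controls and a mean log2 difference of −0.58 (camera adjusted p = 2.43e-08, and adjusted p = 0.569 with an estimated correlation). Their mean was −0.45 without 0.3 ppb replicate 2, and −1.01 and −0.14 on scan days 1 and 2.

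These 3 probes, all higher, were the only ones of 119712 past the threshold (limma adjusted p = 0.0360 for each), with log2 differences of 2.01 (SE 0.24), 3.02 (SE 0.36) and 1.23 (SE 0.14). With the slide as a replicate block, limma called 0 probes, their adjusted p being 0.218, 0.165 and 0.147. With the replicate block, an intensity trend and robust variance together, a setting added after the data were seen, it called 3, 2 and 3 probes at 0.3, 3 and 30 ppb, among them the 3, 2 and 2 called without a block. The unadjusted count under 0.05 was 2223 (1.86%) without and 6596 (5.51%) with the block. In the simulation with slide differences, unchanged probes rose likewise, from 1.18% without to 4.96% with the block. On scan days 1 and 2 taken apart, the differences were 1.68 and 2.34 for A_15_P485237, 3.21 and 2.82 for A_15_P251196, and 1.32 and 1.14 for A_15_P253096.

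**Figure D2:**
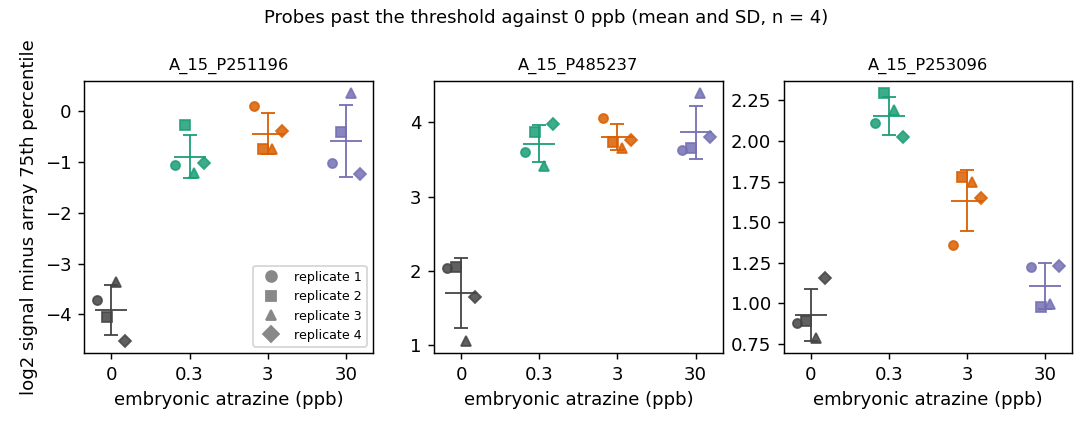
Log2 signal minus the array's 75th percentile of the 3 probes past the threshold against 0 ppb, by dose; points are single brains shaped by replicate and bars are mean and SD of 4. A_15_P251196 averages −3.91 in controls and −0.89, −0.45 and −0.58 in exposed fish, and A_15_P485237 averages 1.70 against 3.71, 3.80 and 3.87.

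Of the 227 genes named by the rule over all comparisons, 0 passed the threshold with limma, so the values that follow are given without a call. Among the 10 higher genes of smallest unadjusted p at 0.3 ppb were fblim1, a LIM protein of actin-linked adhesions (log2 difference 1.74, SE 0.37, while its other probes averaged 0.11), the calpain protease gene capn7 (3.91, SE 0.98), the CTP synthase gene ctps1b (2.55, SE 0.55), the phospholipid acyltransferase gene mboat7 (1.73, SE 0.42) and gstk4, a glutathione transferase (1.64, SE 0.38, while its other probe differed by 4.39). Among the 10 lower ones were gnl2, a nucleolar GTPase of ribosome assembly (−1.70, SE 0.37), the class I myosin gene myo1eb (−1.99, SE 0.61) and pomca, the precursor of corticotropin, melanotropin and endorphin (−1.47, SE 0.38). The pomca signal was −0.47 ± 0.95 against 1.00 ± 0.55. It passed when adjusted over the list alone among pituitary hormones (limma adjusted p = 0.0290) and the corticosteroid stress axis (limma adjusted p = 0.0367), and it was the only member of any list to do so at any dose, whereas 0 list members passed over all probes.

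Many of these genes are neighbours. At 2-fold or more and an unadjusted p under 0.01 against 0 ppb at some dose, 25 genes stood out, and 9 of them lay in one stretch of a single chromosome that spans 70 measured genes. These were rbp5, gstk4, mboat7, gnl2, tent5ba, ptprub, ctps1b, capn7 and myo1eb, 6 higher and 3 lower at 0.3 ppb. Of the 61 other genes of the stretch, 12 (19.7%) had an unadjusted p under 0.05 at 0.3 ppb, 2 (3.28%) at 3 ppb and 1 (1.64%) at 30 ppb, against 1.87%, 1.33% and 1.19% of 13372 genes elsewhere. As differences from the control mean, averaged with the sign each gene had at 0.3 ppb, the 9 genes lay at 1.76 to 2.14 log2 units on all 4 arrays of 0.3 ppb and at −0.11 to 0.11 in controls. The gap between 0.3 ppb and controls follows from how the genes were picked. The 3 ppb fish lay at 1.14, 2.07, −0.04 and −0.23, and the 30 ppb fish at −0.04, 1.21, −0.09 and 1.07.

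**Figure D3:**
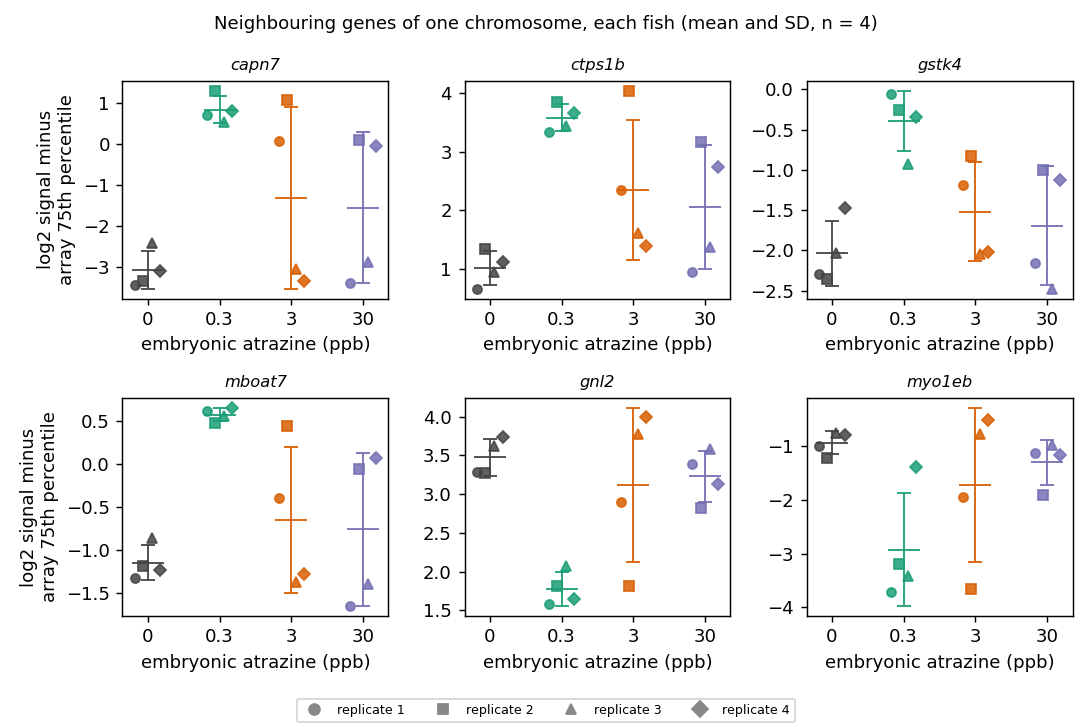
Log2 signal minus the array's 75th percentile of 6 neighbouring genes of one chromosome stretch, by dose; points are single brains shaped by replicate and bars are mean and SD of 4. For capn7 the 0.3 ppb brains average 0.84 and the controls −3.06, while 4 of the 8 brains of 3 and 30 ppb lie near the controls.

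At 0.3 ppb 10 of 35 lists passed with the preset correlation, 3 higher and 7 lower, and 0 with an estimated correlation (smallest adjusted p = 0.569) or with fry (smallest adjusted p = 0.836). Among the 25 neuropeptides, crhb (corticotropin-releasing hormone) differed by −0.34 (SE 0.12) and pdyn (the dynorphin precursor) by −1.04 (SE 0.38), or −0.56 without 0.3 ppb replicate 2. The list's mean was −1.01 on scan day 1 and −0.14 on scan day 2, where it did not pass (adjusted p = 0.393). In 1 of the 4 fish, 0.3 ppb replicate 2, markers of hypothalamic identity were also low: 28 transcription factors had a median of −0.75 against the median of all arrays, with vax1 at −4.17 and fezf1 at −4.01. Without that fish the neuropeptide mean was −0.45. The transcription factor medians of 0.3 ppb replicates 1, 3 and 4 were −0.18, −0.01 and −0.14, against −0.01 to 0.19 in controls.

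At 0.3 ppb the reproductive neuroendocrine axis was lower as a list, with a mean of −0.29 and 19 of 27 genes below controls (adjusted p = 0.00188, and adjusted p = 0.678 with an estimated correlation). Its members esr2a (an estrogen receptor) and tac3a (neurokinin B) differed by −0.30 and −0.56, cyp19a1b (brain aromatase) by −0.43, and kiss1 and kiss2 (kisspeptins) by −1.12 and −1.29. Without 0.3 ppb replicate 2 these were −0.22, −0.24, −0.15, −0.40 and −0.25, and the list's mean was −0.49 on scan day 1 and −0.09 on scan day 2 (day 2 adjusted p = 0.555). The serotonin system had a mean of −0.24, with 15 of 21 lower (adjusted p = 0.00806, and adjusted p = 0.569 with an estimated correlation), and its members htr1d (a serotonin receptor) and slc6a4b (a serotonin transporter) differed by −0.39 and −0.61. On scan days 1 and 2 its mean was −0.25 and −0.23, and it did not pass on day 2 (adjusted p = 0.204). The dopamine and noradrenaline system had a mean of −0.15, with 18 of 24 lower (adjusted p = 0.0226, and adjusted p = 0.569 with an estimated correlation), but 0.04 under median scaling. Its members th2 (a tyrosine hydroxylase) and slc6a3 (the dopamine transporter) differed by −1.24 and −0.71, or by −0.64 and −0.34 without 0.3 ppb replicate 2. The list's mean was −0.25 on scan day 1 and −0.05 on scan day 2 (day 2 adjusted p = 0.818). Pituitary hormones had a mean of −0.46, with 11 of 15 lower (adjusted p = 0.0269, and adjusted p = 0.942 with an estimated correlation), at −0.02 on scan day 1 and −0.90 on scan day 2. Without single arrays the pituitary mean ran from −0.74 to −0.16, and the call ended without 0 ppb replicate 3 (−0.16, adjusted p = 0.281), 0.3 ppb replicate 1 (−0.24, adjusted p = 0.101) or 0 ppb replicate 4 (−0.24, adjusted p = 0.142). Leaving out 0.3 ppb replicate 2 ended 7 of the 10 calls, with means of −0.16 for the reproductive axis and for serotonin and −0.09 for dopamine.

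Cytosolic ribosomal protein genes were higher in 79 of 79 members, with a mean of 0.15 (adjusted p = 3.11e-08, and adjusted p = 0.942 with an estimated correlation), with rpl12 at 0.41 (SE 0.14). Nuclear genes of oxidative phosphorylation were higher in 65 of 72, with a mean of 0.13 (adjusted p = 1.70e-06, and adjusted p = 0.942 with an estimated correlation), with ndufs8a at 0.48. Without 0.3 ppb replicate 2 their means were 0.05 and 0.00 and neither list passed. The ribosomal mean was 0.24 on scan day 1 and 0.06 on scan day 2, where it did not pass (adjusted p = 0.115). Cerebellar genes had a mean of 0.18, with 24 of 33 higher (adjusted p = 0.0444, and adjusted p = 0.942 with an estimated correlation), with ptf1a (a transcription factor of cerebellar inhibitory neurons) at 0.95 and zic4 at 0.65. Their list's means by scan day were 0.21 and 0.15 (day 2 adjusted p = 0.236). Meninges and connective tissue genes had a mean of −0.19, with 26 of 35 lower (adjusted p = 0.0269, and adjusted p = 0.802 with an estimated correlation), but 0.0044 under median scaling and −0.12 and −0.26 by scan day (adjusted p = 0.0968 and 0.0571). The prostaglandin D synthase gene ptgdsb.1 differed by −0.68 (SE 0.21). Without 0 ppb replicate 3 the means of cerebellum, meninges and oxidative phosphorylation were 0.10, −0.05 and 0.07 and none passed (adjusted p = 0.476, 0.130 and 0.0506).

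Other settings ended further list calls at 0.3 ppb. With quantile scaling the reproductive axis (−0.13), serotonin (−0.12), dopamine (−0.03), meninges (−0.08), cerebellum (0.16) and oxidative phosphorylation (0.05) no longer passed (adjusted p = 0.0619, 0.0783, 0.140, 0.0877, 0.229 and 0.0597), and the ribosomal mean was 0.06. With the normexp background the reproductive axis, pituitary hormones, serotonin, dopamine and meninges still passed, at −0.17, −0.20, −0.10, −0.09 and −0.10. Array weights ended the calls of pituitary hormones, cerebellum, meninges and oxidative phosphorylation (adjusted p = 0.407, 0.613, 0.407 and 0.139), and so did the compression covariate, which was added after the data were seen (adjusted p = 0.529, 0.309, 0.151 and 0.0841). With the mean of all probes of a gene pituitary hormones and serotonin did not pass (adjusted p = 0.102 and 0.0543). With the filter on all 16 arrays pituitary hormones and cerebellum did not (both adjusted p = 0.0508).

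Skin and other epithelial genes, which brain tissue hardly expresses, were lower than in controls at every dose, with means of −1.23, −0.999 and −0.70 at 0.3, 3 and 30 ppb and 33, 33 and 28 of 35 genes lower. The adjusted p was 2.29e-15, 2.39e-15 and 1.30e-06 with the preset correlation, and adjusted p = 0.569, 0.569 and 0.880 with an estimated correlation. The keratin gene krt97 differed by −3.28, −2.62 and −2.39. Keratins stood far above the other arrays in 3 brains, at a mean deviation of 4.03 and 3.56 in 0 ppb replicates 1 and 4 and 3.81 in 30 ppb replicate 1, while the other 13 ran from −1.76 to 0.23. The skin list deviated by 1.55 and 1.59 in those 2 controls and by −0.35 and 0.13 in 0 ppb replicates 2 and 3. Without 0 ppb replicate 1 the 30 ppb mean was −0.42 and no longer passed (adjusted p = 0.119). It was −1.19 without 30 ppb replicate 1, −1.06 without 0 ppb replicate 2, −0.41 without 0 ppb replicate 4 and −0.39 without 30 ppb replicate 2. At 30 ppb it was −0.29 on scan day 1 (adjusted p = 0.239) and −1.10 on scan day 2.

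**Figure D4:**
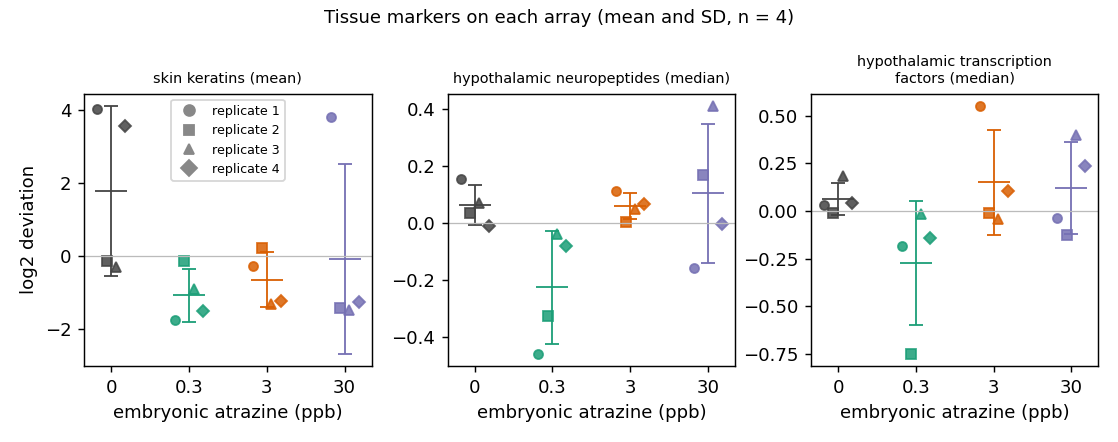
Log2 deviation of each array, by dose, for skin keratins, hypothalamic neuropeptides and hypothalamic transcription factors. Keratins are the mean of 7 genes, each taken from its mean over all 16 arrays. The other panels are medians, each gene taken from its median over all 16 arrays. Points are single brains and bars are mean and SD of 4. Keratins exceed 3.5 in 3 brains, and the transcription factors are lowest, at −0.75, in 0.3 ppb replicate 2.

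At 3 ppb the same comparison was made for the middle dose, and both called transcripts lacked a gene name in the table used. The probe described as caytaxin a was 4.29-fold higher (log2 difference 2.1, SE 0.24, limma adjusted p = 0.0324) and A_15_P251196 was 11-fold higher (3.47, SE 0.36, adjusted p = 0.0189), each above all controls in 4 of 4 brains. Erythrocyte genes were lower as a group, with 23 of 30 below controls and a mean of −0.44 (camera adjusted p = 1.46e-07, and adjusted p = 0.745 with an estimated correlation). Among them the erythropoietin receptor gene epor differed by −0.88 (SE 0.49) and the spectrin gene sptb by −0.61 (SE 0.35). The list's mean was −0.54 on scan day 1 and −0.34 on scan day 2, where it did not pass (adjusted p = 0.115).

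Besides skin and erythrocytes, 2 lists passed at 3 ppb, ribosomal proteins (mean 0.10, 73 of 79 higher, adjusted p = 0.00285, and adjusted p = 0.942 with an estimated correlation) and oxidative phosphorylation (mean 0.12, 62 of 72 higher, adjusted p = 0.00637, and adjusted p = 0.942 with an estimated correlation). Without 0 ppb replicate 3 their means were 0.05 and 0.05, without 3 ppb replicate 2 they were 0.07 and 0.07, and neither passed; the ribosomal mean without 3 ppb replicate 1 was 0.02. With quantile scaling the means were 0.03 and 0.04 and neither passed (adjusted p = 0.263 and 0.525). The compression covariate also ended both calls (adjusted p = 0.580 and 0.558), and array weights ended that of oxidative phosphorylation (adjusted p = 0.106). By scan day the ribosomal means were 0.19 and 0.01 (day 2 adjusted p = 0.643) and those of oxidative phosphorylation 0.14 and 0.09 (day 1 adjusted p = 0.312). The higher genes of smallest unadjusted p included fblim1 (1.59, SE 0.37, while its other probes averaged 0.26), the meiotic recombination gene spo11 (1.33, SE 0.40) and acvrl1, a receptor of the bone morphogenetic protein family in vessels (0.71, SE 0.22). The lower genes of smallest unadjusted p included lsr, a protein of epithelial junctions (−1.74, SE 0.55), hs6st3b, a heparan sulfate sulfotransferase (−0.61, SE 0.18), got1, an aspartate aminotransferase (−0.50, SE 0.15), and the ceramide synthase gene cers4a (−0.71, SE 0.25), whose other probes averaged 0.94. The corticotropin-releasing hormone binding protein gene crhbp differed by −0.52 (SE 0.21). With the replicate block limma called 0 probes at 3 ppb (adjusted p = 0.289 and 0.129 for both probes). The unadjusted count under 0.05 was 1579 (1.32%) without and 4020 (3.36%) with the block, against 4.96% of unchanged probes in the simulation with the block. The differences on scan days 1 and 2 were 1.85 and 2.35 for A_15_P485237 and 3.56 and 3.37 for A_15_P251196.

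At 30 ppb the probe described as caytaxin a was 4.48-fold higher (2.16, SE 0.24) and A_15_P251196 was 10.1-fold higher (3.34, SE 0.36), both at limma adjusted p = 0.0228 and above all controls in 4 of 4 brains. Oligodendrocyte and myelin genes were higher as a group, with 20 of 23 above controls and a mean of 0.19 (camera adjusted p = 0.0269, and adjusted p = 0.942 with an estimated correlation). Cell cycle and neurogenesis genes had a mean of 0.15, with 38 of 49 higher (adjusted p = 0.0285, and adjusted p = 0.942 with an estimated correlation). With the replicate block both missed the threshold (adjusted p = 0.0660 and 0.0773). On scan day 1 their means were 0.08 and 0.05 (adjusted p = 0.606 and 0.518), against 0.30 and 0.24 on scan day 2. The oligodendrocyte mean was 0.12 without 0 ppb replicate 3 (adjusted p = 0.581) and 0.12 without 30 ppb replicate 3 (adjusted p = 0.135). The cell cycle mean was 0.04 without 30 ppb replicate 3 (adjusted p = 0.453) and 0.08 without 0 ppb replicate 2 (adjusted p = 0.345), but 0.26 without 30 ppb replicate 1. With the mean of all probes of a gene the oligodendrocyte and cell cycle means were 0.10 and 0.04 and neither passed (adjusted p = 0.0695 and 0.115). Array weights and the compression covariate ended the oligodendrocyte call (adjusted p = 0.106 and 0.151). The claudin gene cldnk of myelin differed by 0.49 and the cyclin gene ccna2 by 0.46.

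Ribosomal protein genes were again higher at 30 ppb in 73 of 79 members (mean 0.10, adjusted p = 0.00188, and adjusted p = 0.942 with an estimated correlation), at 0.14 on scan day 1 and 0.07 on scan day 2 (day 2 adjusted p = 0.236). Skeletal muscle genes had a mean of −0.25, with 37 of 51 lower (adjusted p = 0.0144, and adjusted p = 0.942 with an estimated correlation), but 0.11 without 0 ppb replicate 3, and −0.07 on scan day 1 (adjusted p = 0.376) against −0.42 on scan day 2. Genes of the glutamate system had a mean of −0.10, with 18 of 23 lower (adjusted p = 0.0269, and adjusted p = 0.718 with an estimated correlation), but 0.05 under median scaling, 0.02 on scan day 1 and −0.23 on scan day 2. Without 0 ppb replicate 3 the ribosomal and glutamate means were 0.05 and −0.02 (adjusted p = 0.450 and 0.281), and without 30 ppb replicate 2 the ribosomal mean was 0.03 (adjusted p = 0.908). Array weights ended the calls of ribosomal proteins, muscle and glutamate (adjusted p = 0.923, 0.682 and 0.109), and the compression covariate those of ribosomal proteins and muscle (adjusted p = 0.581 and 0.178). With the mean of all probes of a gene muscle and glutamate did not pass (adjusted p = 0.0622 and 0.0652), nor did glutamate with outlier spots kept (adjusted p = 0.0592). The higher genes of smallest unadjusted p included fblim1 (1.94, SE 0.37, while its other probes averaged 0.35), the Notch ligand jag1a (0.60, SE 0.13), the membrane metalloproteinase mmp14a (0.58, SE 0.15), ceruloplasmin, cp (0.85, SE 0.24), rbp4, the retinol carrier (0.88, SE 0.26), and igfbp2a, an insulin-like growth factor binding protein (0.57, SE 0.16). The lower genes of smallest unadjusted p included agxta, an aminotransferase (−1.13, SE 0.35), ccnf, an F-box cyclin (−1.15, SE 0.44), and the methionine adenosyltransferase gene mat2ab (−1.31, SE 0.48). With the replicate block limma called 0 probes at 30 ppb (adjusted p = 0.217 and 0.188 for both probes). The unadjusted count under 0.05 was 1363 (1.14%) without and 3880 (3.24%) with the block, against 4.96% of unchanged probes in the simulation with the block. The differences on scan days 1 and 2 were 1.59 and 2.74 for A_15_P485237 and 3.17 and 3.51 for A_15_P251196.

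**Figure D5:**
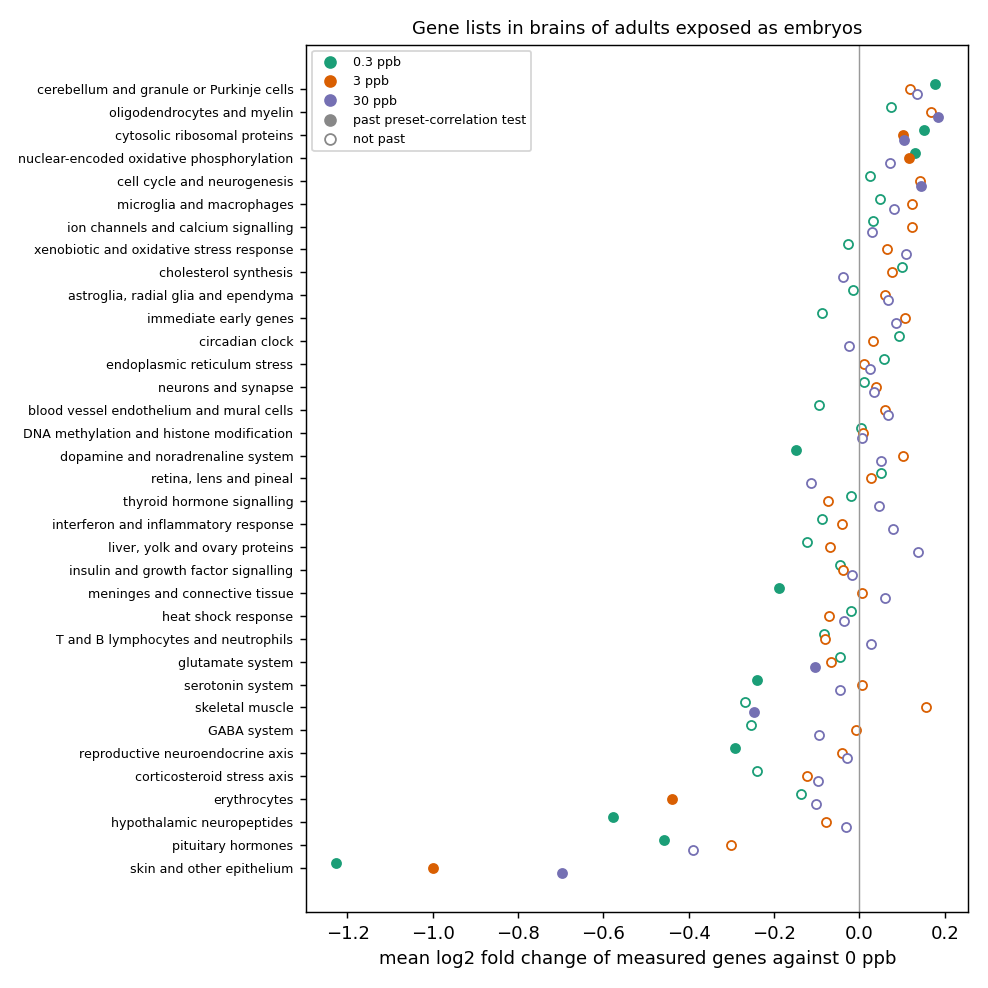
Mean log2 fold change against 0 ppb of the measured genes of 35 lists, by dose; filled points passed the test with a preset correlation and open points did not. Skin and other epithelium lies lowest, at −1.23, −0.999 and −0.70.

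The lists and genes of hormone and stress pathways showed no dose that passed beyond those above. At 3 and 30 ppb the neuropeptide means were −0.08 (adjusted p = 0.203) and −0.03 (adjusted p = 0.530), and those of the reproductive axis −0.04 (adjusted p = 0.211) and −0.03 (adjusted p = 0.299). Those of pituitary hormones were −0.30 (adjusted p = 0.0785) and −0.39 (adjusted p = 0.0581, 0.0387 with the replicate block, and adjusted p = 0.927 with the block and an estimated correlation). The means of the corticosteroid stress axis were −0.24, −0.12 and −0.10 from the lowest to the highest dose (adjusted p = 0.125, 0.0707 and 0.280). The means of DNA methylation and histone genes were 0.00, 0.01 and 0.01 (adjusted p = 0.735, 0.923 and 0.879), with dnmt1 at 0.15, 0.13 and 0.15 and dnmt3aa at 0.15, 0.33 and 0.08. Brain aromatase cyp19a1b differed by 0.09 and 0.15 at the higher doses, pomca by −0.39 and −0.09, and crhb by −0.22 and −0.06. The estrogen receptor esr1 differed by −0.41, 0.00 and −0.17, esr2b by −0.07, 0.05 and 0.02, and the androgen receptor ar by 0.25, 0.02 and 0.17. The hypothalamic gene npvf differed by −0.79, 0.45 and 0.17, gnrh2 by −0.64, 0.12 and 0.33, gnrh3 by −0.04, 0.03 and 0.30, kiss1 by −0.45 and −0.27 at the higher doses and kiss2 by −0.02 and −0.04. Without 0.3 ppb replicate 2 the 0.3 ppb values of esr1, npvf and gnrh2 were 0.13, −0.45 and −1.22. The serotonin genes tph2 and slc6a4a differed by 0.33, 0.36 and 0.30 and by 0.00, 0.17 and −0.17, th by −0.04, 0.16 and 0.16, and th2 by 0.05 and 0.06 at the higher doses. The glucocorticoid receptor nr3c1 differed by −0.08, −0.17 and −0.02.

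Between doses, the fish differed at 0 probes in each pair with limma, with 799 probes at an unadjusted p under 0.05 for 3 against 0.3 ppb, 1321 for 30 against 0.3 ppb and 707 for 30 against 3 ppb, and with the replicate block at 0 probes (2140, 3015 and 1861). The F test over all doses called A_15_P251196 and A_15_P485237 (2 probes, adjusted p = 0.0385; 966 at an unadjusted p under 0.05) and 0 with the block (3021). The slope over dose steps called 0 probes with limma (1530, and 3575 with the block). By smallest p the F test put fblim1, jag1a, gnl2, znfl1b and ctps1b first among named genes, and the slope put jag1a (0.20 per step), mmp14a (0.19), fblim1 (0.57), cp (0.27) and rbp4 (0.29), none of them past the threshold. At 0.3 ppb znfl1b differed by 1.32 while its other probes averaged 0.08, and ctps1b by 2.55 with its other probe at 2.26.

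Across 13442 genes, which are not independent replicates, the fold changes against 0 ppb correlated at r = 0.67 between 0.3 and 3 ppb, 0.67 between 0.3 and 30 ppb and 0.67 between 3 and 30 ppb. Unchanged groups simulated against the same 4 controls gave r = 0.50 each, and 100 regroupings of the arrays gave r up to 0.946, 0.936 and 0.904. The covariance was 0.0663, 0.0700 and 0.0561, against a simulated 0.0908, 0.0910 and 0.0913, and 40, 35 and 45 of the 100 regroupings gave one as large. Both references count slide differences as noise, although these cancel in the real fold changes, since every slide held all doses. In references added later, noise left after the replicate block gave a covariance of 0.0519, 0.0519 and 0.0521. With doses exchanged within each slide, 171, 127 and 252 of 1000 regroupings, the real one included, gave a covariance as large, and 137, 112 and 133 an r as large. With 2 separate controls for each dose r ran from −0.55 to 0.24, from −0.51 to 0.25 and from −0.57 to 0.13 over the 6 ways of sharing out the controls. Each set of 2 controls came from 2 of the 4 slides, so slide differences did not cancel there and entered both fold changes with opposite signs. That lowers r whatever the doses did, so these values cannot show how much of the 0.67 came from shared controls. Each pair of doses shared 2 called probes, all against the same controls. In a count added after the calls were seen, 6, 7 and 5 of 100 regroupings of the arrays shared as many. With the doses exchanged within each slide 3, 2 and 3 of 100 did, the real grouping being included in each of these counts.

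The probe lists that the authors deposited held 446, 338 and 317 probes for 0.3, 3 and 30 ppb, with 252, 205 and 183 higher and every absolute fold at 1.5 or more. They were drawn from these arrays, so they are no independent evidence. All had the same direction here, and 3, 2 and 2 passed limma's adjusted threshold, while 395, 238 and 223 of those tested had an unadjusted p under 0.05. The 0.3 and 3 ppb lists shared 242 probes, the 0.3 and 30 ppb lists 187, and the 3 and 30 ppb lists 190, all of them set against the same controls. Of the tested probes with a gene name, which alone can be placed, 29 of 116, 16 of 80 and 8 of 72 lay in the chromosome stretch above. Over the 8 arrays of 3 and 30 ppb, 15.5%, 12.3% and 7.34% of all tested probes of the lists followed the stretch's average at a correlation above 0.8, against 1.36% of all probes. These shares include probes of the stretch itself, among them genes that make up the average, so part of the excess follows by construction.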

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

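A value was taken up here when 1 array lay so far from the other 3 of its dose that the gap, as a share of the group's whole range, exceeded the 95% critical value of Dixon's test. Of 260 groups checked 11 did so, and chance alone flags about 1 in 20, or 13. Skeletal muscle genes were highest in 0 ppb replicate 3 (gap 0.852 of the range; list deviation 1.17, next −0.16), and that array also had the highest negative control signal (0.831; 51.1, next 27). In 0.3 ppb replicate 2 the kisspeptin genes were lowest, kiss1 at −6.53 (0.876; next −3.88) and kiss2 at −4.43 (0.897; next −0.46). In 3 ppb replicate 2 the microglia and macrophage list was lowest (0.887; −0.51, next 0.19), as were the blood vessel list (0.858; −0.12, next 0.09) and the detoxification gene cyp1a (0.839; −5.78, next −2.85), while the endoplasmic reticulum stress list was highest (0.856; 0.13, next −0.04). The xenobiotic and oxidative stress list was lowest in 0.3 ppb replicate 1 (0.922; −0.31, next 0.01). The gonadotropin-releasing hormone gene gnrh2 was highest in 3 ppb replicate 1 (0.848; 2.53, next 2.07) and gnrh3 in 3 ppb replicate 4 (0.909; −2.11, next −3.34).

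The 3 patterns weighed next and their marker genes were picked after the values had been seen, and so were the tests of a response of every exposed fish, of lower keratins in exposed fish and of lower neuropeptides in all 0.3 ppb fish. The first is the chromosome stretch of capn7, ctps1b and 7 more genes. Of the 25 genes furthest from controls 11 lay near another member, against at most 8 in 10000 random sets (permutation share 1e-04, the smallest possible). Of the 8 fish of 3 and 30 ppb, 1 lay at the level of the 0.3 ppb fish (2.07), 3 between (1.07, 1.14 and 1.21) and 4 at that of the controls, and over these arrays the 9 genes moved together at a mean signed correlation of 0.884, against at most 0.755 in random sets. For these 9 genes the values argue against a response of every exposed fish, since 4 of the 8 stayed at the control level. The genes were picked on their values at 0.3 ppb, and a response at that dose alone or in some fish only was not excluded. The values suggest (0.884) a stretch inherited in different versions by different fish; differences in sequence under the probes and differences in expression were not told apart, and no genotype was analysed here.

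The second pattern is the keratin signal of 3 brains. Over the 16 arrays the skin list followed a second list of 25 epidermal genes (permutation p = 3e-05 for rho = 0.862, p = 0.0013 for r = 0.724, and r = 0.641 without the 2 farthest arrays), as skin carried over with the brain at dissection would make it do. The permutation moved arrays freely across slides, so its p does not allow for differences between slides. On slide 2 the skin list lay at −0.88 to −0.34 and the second list at −0.44 to −0.19. Agreement through the slides was not tested apart from carried-over skin. The second list did not single out the same 3 brains, though: it was 0.58, 0.22 and 0.23 in 0 ppb replicates 4 and 1 and 30 ppb replicate 1, against 0.45 in 0 ppb replicate 3 and 0.23 in 30 ppb replicate 4, where keratins were low. In 8 of 12 exposed brains keratins lay below the lowest control. Carried-over skin and a lower keratin level in exposed fish cannot be told apart from these values.

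The third pattern is the low neuropeptide signal of 0.3 ppb replicate 2, where avp was at −4.59, oxt at −4.43 and pmchl at −3.79 from the median of the 16 arrays and the neuropeptide median was −0.33. Hypothalamic transcription factors, which mark the tissue, had a median of −0.75 there, the lowest of 16, with 11 of 28 more than 1 lower, which fits less hypothalamus in that sample. Lower neuropeptides in all 0.3 ppb fish could not be decided: without that array the mean difference was −0.45, or 0.773 of that with it, and 0.3 ppb replicate 1 had a neuropeptide median of −0.46, but replicates 3 and 4 were at −0.04 and −0.08, near the controls at −0.01 to 0.15. In 0.3 ppb replicate 1 the transcription factor median was −0.18, against −0.01 to 0.19 in controls.

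Whether the counts of calls exceed chance was examined by regrouping the same arrays, and the regroupings within slides were added after the other counts had been seen. Between 0.3 and 0 ppb, 2 of 35 ways to split the 8 arrays gave as many probes as the real 3 (highest other 3). For 3 ppb 2 of 35 did (real 2, highest other 7112), and for 30 ppb 3 of 35 (real 2, highest other 29124, the split by scan day; with the replicate block the real grouping gives 0). For the F test 12 of 100 regroupings, the real one included, gave as many as 2 (highest other 21769). The splits with 7112 and 29124 probes did not share out every slide between the groups, which points to the structure of slides and scan days. Of the 8 splits that share out all 4 slides as the real one does, only the real one reached its count at each dose (highest other 0, 0 and 0), but 8 are too few for a share under 0.05. With doses exchanged within each slide, 9 of 100 regroupings, the real one included, gave as many as 2 in the F test (highest other 4). For lists 19, 34 and 30 of 35 splits gave as many as the real 10, 4 and 6 (highest other 15, 13 and 16), and 3, 7 and 7 of the 8 within slides (highest other 13, 10 and 10). Chance cannot be excluded for the probe counts at each dose over all 35 splits, for the F test or for the lists. Where the real count is 0 every split reaches it by construction (35 of 35 between each pair of doses and 100 of 100 for the slope; highest other 3, 1, 9 and 1), so these decide nothing.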

How the results depend on the processing

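The added alternatives were chosen after seeing the data: outlier spots kept, a quality set of 2 arrays left out (0 ppb replicate 3 and 3 ppb replicate 1), a skin set of 3 left out (0 ppb replicates 1 and 4 and 30 ppb replicate 1), a covariate for signal compression, scan day 1 or 2 alone, the replicate block with a trend and robust variance or with an estimated correlation, and the fold-change correlation under other scalings. A_15_P251196, A_15_P253096 and A_15_P485237 kept their direction in all 32 alternatives at 0.3 ppb, with log2 differences of 2.01 to 3.28, 1.14 to 1.42 and 1.68 to 2.34, and stayed past the threshold in 9, 12 and 11. At 3 ppb A_15_P251196 and A_15_P485237 ran from 2.37 to 3.73 and 1.80 to 2.35 and stayed past it in 17 and 12, and at 30 ppb they ran from 2.28 to 3.69 and 1.59 to 2.74 and stayed past it in 17 and 14. Probe counts of 3, 2 and 2 for 0.3, 3 and 30 ppb and 2 for the F test became 0, 0, 0 and 0 with the replicate block, which changed no other probe call. With the scan day block 0.3 ppb and F gave 0 and 0; with normexp 30 ppb and F gave 1 and 1; with median scaling 0.3 ppb gave 1; with array weights F gave 4, as with the block, trend and robust variance (4, and 3, 2 and 3 at the doses); with trend and robust variance alone 30 against 0.3 ppb gave 1; with the compression covariate 30 ppb gave 4. Without the quality set the counts were 1, 0 and 0, with F 1 and 30 against 0.3 ppb 1, and without the skin set 1, 1 and 1, with F 0. Scan day 1 alone gave 0 at 0.3 ppb, 1 at 3 ppb, 1 and 1 for 3 and 30 against 0.3 ppb, and F 1; scan day 2 alone gave 1 at 3 ppb, 0 at 30 ppb, and 2 and 2 for 3 and 30 against 0.3 ppb. Only the 2 groups compared gave 16, 0 and 0, and 1 for 30 against 0.3 ppb. Without single arrays the counts ran from 0 to 6 at 0.3 ppb (6 without 3 ppb replicate 2, 1 without 3 ppb replicate 1, 3 without 30 ppb replicate 3, else 0), 0 to 3 at 3 ppb (0 without 0 ppb replicate 1, 2 or 4, 0.3 ppb replicate 1 or 4, any 1 of the 3 ppb arrays or 30 ppb replicate 2, and 1 without 0.3 ppb replicate 2 or 3 or 30 ppb replicate 1 or 4), 0 to 3 at 30 ppb (0 without 0 ppb replicate 1, 2 or 4, 0.3 ppb replicate 1, 3 ppb replicate 2, 3 or 4 or 30 ppb replicate 1 or 2, and 1 without 0.3 ppb replicate 2 or 30 ppb replicate 4), 0 to 3 for F (1 without 30 ppb replicate 4, not below 2 without 3 ppb replicate 2 or 30 ppb replicate 3, else 0), 0 to 2 for 3 against 0.3 ppb (2 without 3 ppb replicate 2), 0 to 1 for 30 against 0.3 ppb (1 without 3 ppb replicate 2) and 0 to 1 for 30 against 3 ppb (1 without 30 ppb replicate 3). List counts of 10, 4 and 6 became 0, 0 and 0 with an estimated correlation, with fry (0, 0 and 0) and with block and estimated correlation (0, 0 and 0). Array weights (8, 4 and 9) and the compression covariate (8, 2 and 5) ended 9 list calls each and added others. At 0.3 ppb the counts became 5 with quantile scaling, 6 without the quality set and 4 on scan day 2 alone, at 3 ppb 2 with the compression covariate and 8 on scan day 1 alone, and at 30 ppb 3 with the mean of all probes. Without single arrays they ran from 4 to 13 at 0.3 ppb (4 without 0.3 ppb replicate 2, 6 without 0 ppb replicate 3), 2 to 8 at 3 ppb (2 without 0 ppb replicate 3) and 4 to 11 at 30 ppb (11 without 30 ppb replicate 2). The replicate block ended the list calls for oligodendrocytes and cell cycle at 30 ppb and added pituitary hormones (adjusted p = 0.0387) and oxidative phosphorylation (adjusted p = 0.0270) at 30 ppb and the circadian clock (adjusted p = 0.0399) at 0.3 ppb, all 3 lost with the block and an estimated correlation (adjusted p = 0.927, 0.927 and 0.906). Median scaling moved the median log2 difference of all genes from 0.02, 0.04 and 0.03 to 0.21, 0.17 and 0.18, so absolute levels depend on the scaling; there the list means turned for dopamine (0.0426) and meninges (0.0044, still past the test as lower than other genes, adjusted p = 0.0262) at 0.3 ppb and for glutamate (0.0464) at 30 ppb, each of them below that median. Without the quality set ribosomal proteins turned at 3 ppb (−0.0305) and skeletal muscle at 30 ppb (0.114); glutamate turned at 30 ppb on scan day 1 alone (0.0249), and skeletal muscle at 30 ppb without 0 ppb replicate 3 (0.114, adjusted p = 0.421; −0.407 to 0.114 without single arrays). Leaving out 1 array ended list calls at these means. At 0.3 ppb these were, without 0.3 ppb replicate 2, the reproductive axis (−0.16), serotonin (−0.16), dopamine (−0.09), meninges (−0.14), cerebellum (0.09), ribosomal proteins (0.05) and oxidative phosphorylation (0.00); without 0 ppb replicate 3, meninges (−0.05), pituitary (−0.16), cerebellum (0.10) and oxidative phosphorylation (0.07); without 0 ppb replicate 1, serotonin (−0.24), dopamine (−0.12) and meninges (−0.29). Further ones were meninges (−0.06), pituitary (−0.24) and cerebellum (0.22) without 0.3 ppb replicate 1, meninges (−0.11) and pituitary (−0.24) without 0 ppb replicate 4, dopamine (−0.15) without 0.3 ppb replicate 3, and cerebellum (0.18) without 3 ppb replicate 1 or 2. At 3 ppb they were ribosomal proteins and oxidative phosphorylation without 0 ppb replicate 3 (0.05 and 0.05) or 3 ppb replicate 2 (0.07 and 0.07), and ribosomal proteins without 3 ppb replicate 1 (0.02). At 30 ppb they were, besides muscle, cell cycle (0.15), oligodendrocytes (0.12), ribosomal proteins (0.05) and glutamate (−0.02) without 0 ppb replicate 3, and cell cycle (0.13), muscle (−0.36) and skin (−0.42) without 0 ppb replicate 1. Cell cycle (0.04), oligodendrocytes (0.12) and glutamate (−0.10) ended without 30 ppb replicate 3, cell cycle (0.11), muscle (−0.33) and glutamate (−0.11) without 30 ppb replicate 4, oligodendrocytes (0.20) and ribosomal proteins (0.10) without 30 ppb replicate 1, cell cycle (0.08) and oligodendrocytes (0.17) without 0 ppb replicate 2, ribosomal proteins (0.03) without 30 ppb replicate 2 and cell cycle (0.15) without 0.3 ppb replicate 2. Without the skin set, picked on keratins and so no test of the skin list, 5 other 0.3 ppb lists did not pass. Neuropeptides at 0.3 ppb and erythrocytes at 3 ppb passed in 32 of 36 settings each without turning, but not with fry or an estimated correlation. The fold-change correlations ran from 0.281 to 0.822, 0.390 to 0.823 and 0.351 to 0.824 without single arrays. Beyond the scaling shift and fewer arrays, the cause was not tested. An array with 79.9% of spots above background says less about weak transcripts than one with 92.7%.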

Other observations

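Several groups of genes followed the slide more than the dose. Immediate early genes, which mark recent neuronal activity, averaged 0.59 on slide 1 and −0.41 on slide 4 as deviations from all arrays. Liver, yolk and ovary proteins averaged −0.74 on slide 2 and 0.55 on slide 3, retina, lens and pineal genes −0.61 and 0.61, pituitary hormones −0.67 and 0.54, lymphocytes and neutrophils −0.62 and 0.36, skeletal muscle −0.49 and 0.40, and interferon genes −0.46 and 0.33, on the same slides. The log2 ratio of an array's 75th percentile to its median signal was 2.64 to 2.84 on slide 2 and 1.55 to 2.29 on slide 3. Whether these lists followed that spread of signal or the tissue was not tested. The activity gene fosab differed from controls by −0.27, 0.43 and 0.30 (SE 0.91) at 0.3, 3 and 30 ppb, the glucocorticoid target fkbp5 by −0.11, −0.52 and −0.36 (SE 1.03), cyp1a by −0.54, −0.37 and −0.47 (SE 1.05) and the clock gene per2 by −0.09, −0.24 and −0.33.

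The other lists stayed short of the threshold without a block, given here as mean log2 difference and adjusted p of limma's camera with the preset correlation for 0.3, 3 and 30 ppb. Transmitter lists were GABA (−0.25, −0.01 and −0.10; adjusted p = 0.156, 0.446 and 0.125), glutamate at the lower doses (−0.04 and −0.07; adjusted p = 0.737 and 0.177), and serotonin (0.01 and −0.05; adjusted p = 0.825 and 0.386) and dopamine (0.10 and 0.05; adjusted p = 0.820 and 0.968) at the higher doses. Signalling lists were thyroid hormone (−0.02, −0.07 and 0.05; adjusted p = 0.770, 0.457 and 0.943), insulin and growth factors (−0.04, −0.04 and −0.02; adjusted p = 0.571, 0.213 and 0.452), ion channels and calcium (0.03, 0.12 and 0.03; adjusted p = 0.363, 0.0785 and 0.770), immediate early genes (−0.09, 0.11 and 0.09; adjusted p = 0.380, 0.852 and 0.931) and the circadian clock (0.09, 0.03 and −0.03; adjusted p = 0.341, 0.911 and 0.340). With the replicate block the clock passed at 0.3 ppb (adjusted p = 0.0399, and adjusted p = 0.906 with the block and an estimated correlation). Stress and metabolic lists were xenobiotic and oxidative stress (−0.03, 0.06 and 0.11; adjusted p = 0.943, 0.477 and 0.203), heat shock (−0.02, −0.07 and −0.04; adjusted p = 0.716, 0.119 and 0.296), endoplasmic reticulum stress (0.06, 0.01 and 0.02; adjusted p = 0.255, 0.943 and 0.812), cholesterol synthesis (0.10, 0.08 and −0.04; adjusted p = 0.344, 0.759 and 0.309) and oxidative phosphorylation at 30 ppb (0.07; adjusted p = 0.0785). With the replicate block the last passed (adjusted p = 0.0270, and adjusted p = 0.927 with the block and an estimated correlation).

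Immune lists were interferon and inflammation (−0.09, −0.04 and 0.08; adjusted p = 0.363, 0.156 and 0.813), microglia and macrophages (0.05, 0.12 and 0.08; adjusted p = 0.363, 0.477 and 0.805) and lymphocytes and neutrophils (−0.08, −0.08 and 0.03; adjusted p = 0.297, 0.0622 and 0.571). Cell type lists of the brain were oligodendrocytes at the lower doses (0.07 and 0.17; adjusted p = 0.548 and 0.125), astroglia (−0.02, 0.06 and 0.07; adjusted p = 0.716, 0.809 and 0.602), neurons and synapse (0.01, 0.04 and 0.03; adjusted p = 0.825, 0.813 and 0.759), cerebellum at the higher doses (0.12 and 0.13; adjusted p = 0.416 and 0.209) and cell cycle at the lower doses (0.03 and 0.14; adjusted p = 0.716 and 0.0707). Lists of other tissues were blood vessel cells (−0.09, 0.06 and 0.07; adjusted p = 0.452, 0.341 and 0.156), erythrocytes at 0.3 and 30 ppb (−0.14 and −0.10; adjusted p = 0.280 and 0.169), meninges at the higher doses (0.01 and 0.06; adjusted p = 0.355 and 0.637), skeletal muscle at the lower doses (−0.27 and 0.16; adjusted p = 0.0707 and 0.809), retina, lens and pineal (0.05, 0.03 and −0.11; adjusted p = 0.931, 0.363 and 0.0707) and liver, yolk and ovary proteins (−0.12, −0.07 and 0.14; adjusted p = 0.355, 0.299 and 0.548). The test ranked genes below the others, against a positive mean, for immediate early genes, serotonin, meninges, circadian clock, retina and endoplasmic reticulum stress at 3 ppb and for thyroid hormone and lymphocytes at 30 ppb. Mean and median had opposite signs for thyroid hormone at 0.3 ppb, lymphocytes, serotonin and retina at 3 ppb and the circadian clock at 30 ppb.

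Single genes of these groups included the interferon-induced GTPase gene gbp1 (2.29 at 0.3 ppb and 1.88 at 3 ppb, and 1.16 at 30 ppb in the authors' list), the cartilage and glia regulator sox9a (1.23, 1.13 and 1.31), the kinase gene camk2a (−0.83 at 0.3 ppb), the growth hormone gene gh1 (−1.5 at 3 ppb) and the vessel receptor gene tek (0.39 at 30 ppb), none past the threshold.

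A search made after seeing the data found 5 probes 2-fold or more from controls in the same direction at all 3 doses with an F p under 0.001, all higher: fblim1 (mean log2 difference 1.75), A_15_P251196 (3.27), A_15_P485237 (2.09), A_15_P446755 (1.65) and A_15_P553517 (2.21). Spots within 5 rows and columns of them on the array had median differences of −0.08 to −0.02. Only fblim1 had other probes, 2 of them, and these moved 0.138 as far. Each dose always took 1 position on the slide, so position and dose cannot be told apart.

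A rule of a plain F p under 0.05 and a 1.5-fold change found 433, 328 and 306 probes at 0.3, 3 and 30 ppb, of which 420, 314 and 289 were on the authors' lists. Among the 127569 probes without a missing value the rule found 432, 325 and 300. When arrays were regrouped at random, 82, 94 and 95 of 100 regroupings gave as many of these probes, and when doses were exchanged within each slide 19, 47 and 53 of 100 did.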
